A study of Homo sapiens with 2 samples.

How the data were processed

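Poly(A) RNA was measured in THP-1 cells, a human acute monocytic leukaemia line that carries a KMT2A fusion. There was 1 library of untreated parental cells and 1 library of cells made resistant to cytarabine (Ara-C), a nucleoside analogue, by raising its concentration stepwise from 5 nM to 10 µM. Per the labels' protocols, libraries were prepared with a dUTP second strand, which keeps the strand of origin, and were sequenced as read pairs. Groups were taken from the titles and treatment labels of the samples.

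The deposited table held 30856 Ensembl gene rows with coordinates, transcript types, an FPKM value with 2 decimals and a whole-number read count for each library. Per the submitters' processing notes, cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d, DESeq2 and edgeR were used with the GRCh38 build, with no role or order given. The annotation release, the strand setting and the handling of reads that map to several places were not given in the sources used here. FPKM as deposited is normalised to transcript length and library size; the deposited counts are not normalised. The resistant count column carried a suffix that the labels do not explain. Over 10850 well covered genes, the FPKM and count log2 ratios correlated at 1.00 across genes and differed by a constant (median -0.025, SD 0.0028), so both columns were taken to describe the same library. Total counts were 57434972 in the parental and 58285463 in the resistant library.

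The measure was log2((FPKM resistant + 1)/(FPKM parental + 1)), with a pseudocount of 1 FPKM, which understates differences of low genes. Genes entered when they had a symbol (22880 rows) and reached an FPKM of 1 in at least 1 library (11388 genes). With 1 library per group no test between conditions is possible, so genes were counted by a rule of size, a log2 ratio of at least 1 or at most -1, written below as at least 2-fold. The design had assumed FPKM values alone. The counts also present were used for depth and for the fold of counts relative to the library total (as CPM), with an exact 95% interval from the Clopper-Pearson interval of the resistant share of a gene's counts. These intervals treat read pairs as independent molecules, which is not known without molecular identifiers. They may thus be too narrow even for counting error, and they cover no spread between cultures.

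For 39 gene lists, the median log2 ratio of the expressed members was set against 10000 random lists of the same size, matched over 20 bins of mean expression. The percentile of the list is a description of these libraries. A list inside the central 95% of its random lists is called inside the random range, and lists with fewer than 5 expressed members got no percentile. Lists, size rule, pseudocount, filters and the rule for named genes were set before the data were examined. Named genes were the 12 protein-coding genes with the highest and the 12 with the lowest log2 ratio among 6406 genes with an FPKM of at least 5 in the higher library, every measured m6A regulator and cytarabine gene, the 3 members of each other list with the largest absolute log2 ratio, and list members that make up a count of 5 or fewer; some of these members are not reported here. Genes named outside this rule, including those that mark positions on chromosomes, were chosen after their values were seen. The scan along chromosomes and the scan of the table's own gene ontology and pathway terms were also added after the data were seen.

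Chromosomes were scanned in windows of 15 consecutive expressed genes against 1000 shuffles of gene order, and the best single break of each chromosome was placed by least squares with at least 20 genes on each side. Coordinates are those of the deposited table. Gene length for checks was derived from counts and FPKM, and GC content came from the longest transcript of each gene in GENCODE for GRCh38, which held 99.9% of the expressed genes.

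The steps were tested on simulated counts for 10973 genes drawn from the real means and library sizes, with counting noise alone and 200 genes changed by known folds. For this comparison, 50 of 50 genes with a true 3-fold difference passed the 2-fold rule, 2 of 50 with a true 2-fold difference did, as the pseudocount shrinks ratios, and 2 of 10733 genes with no difference did. The changed genes all had a mean of at least 5 FPKM. Detection of lower genes, whose ratios the pseudocount shrinks more, was thus not simulated. The simulated counts were independent within and between genes, which real libraries need not be. Under that condition the counting intervals held the true fold for 95.4% of the genes. Of 200 lists with no shift, 4% lay outside the random range. Alternatives covered the pseudocount, the filter on low values, scaling, the size rule, gene classes and the random lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.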

Results

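The study set cytarabine-resistant THP-1 cells beside their parental line, with the regulators of N6-methyladenosine (m6A), a methyl mark on messenger RNA, as its subject. The parental library held 57434972 counts over 24445 genes and the resistant library 58285463 counts over 24132 genes. Mitochondrial transcripts took 5.96% and 5.92% of the counts, and the 10 most abundant genes took 6.78% and 6.98%, in parental and resistant cells. The mitochondrial ribosomal RNAs took 0.552% and 0.741%. There were no replicates, so every difference below compares 2 libraries and has no replicate check.

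The resistant cells differed from the parental cells in a small set of genes, with myeloid calcium-binding proteins among the lowest and a receptor tyrosine kinase among the highest. S100A9 and S100A8, the subunits of calprotectin, were 10.0-fold lower (95% counting interval 9.56 to 10.5) and 6.84-fold lower (6.26 to 7.48) in resistant cells. AXL, a receptor tyrosine kinase, was 5.76-fold higher (5.31 to 6.27), at 11.1 FPKM against 1.92. The interferon-induced gene IFI27 was 19.2-fold higher (15.7 to 23.9), and the antioxidant enzyme PRDX2 was 4.76-fold lower (4.41 to 5.14). Of 11388 expressed genes, 72 were at least 2-fold higher and 140 at least 2-fold lower in resistant cells. On the FPKM + 1 scale, which shrinks differences of low genes, 92.3% of the 11388 genes were less than 1.5-fold apart. The SD of the log2 ratio was 0.34 on this scale. The folds with intervals above are ratios of counts relative to the library total, without a pseudocount. Pearson's r of log2(FPKM + 1) across genes was 0.976 (Spearman's rho 0.969), genes not being independent replicates. The count of 212 genes depended on the pseudocount: it was 592 with 0.1 FPKM and 30 with 5 FPKM.

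**Figure D1:**
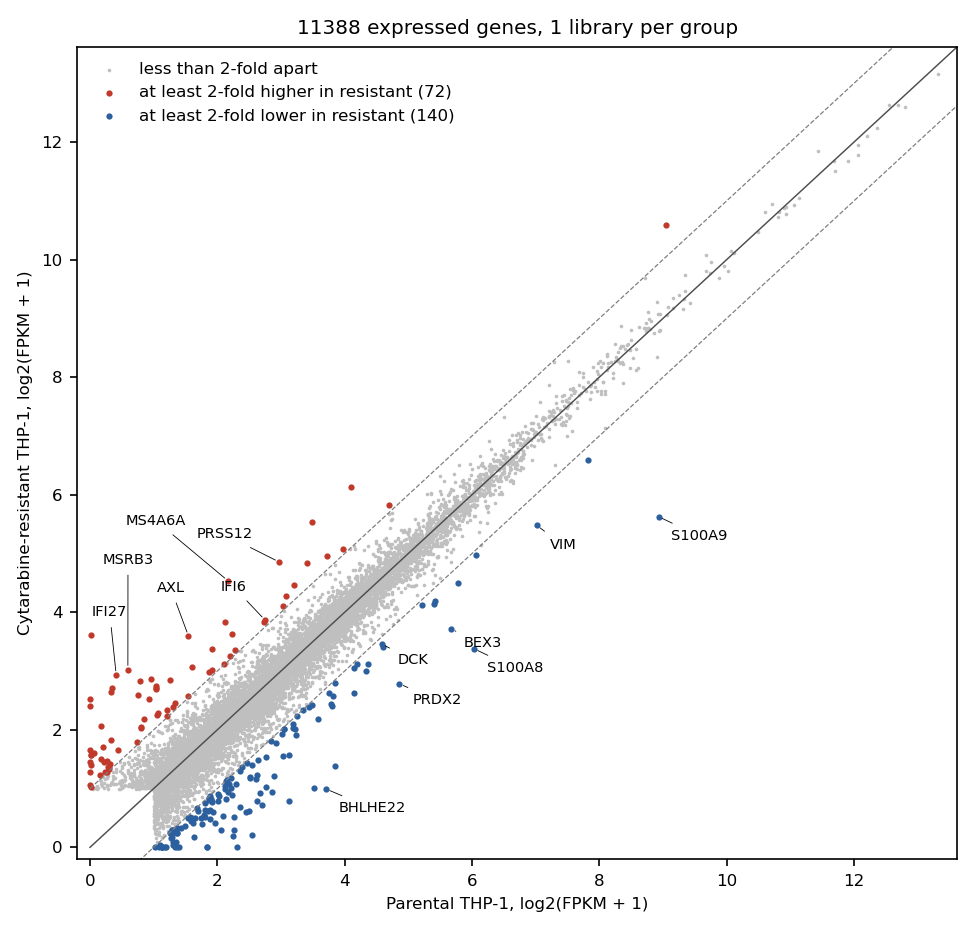
Each point is 1 of the 11388 expressed genes, with log2(FPKM + 1) of the parental library on the x axis and of the resistant library on the y axis. The solid line marks equal levels and the dashed lines a 2-fold difference on this scale; 72 genes lie above the upper and 140 below the lower dashed line.

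Among the 12 protein-coding genes highest in resistant cells, AXL and IFI27 were joined by MSRB3, a methionine sulfoxide reductase, at 7.14 FPKM against 0.51 in parental cells. The membrane protein gene MS4A6A stood at 22.2 against 3.49 FPKM, the serine protease gene PRSS12 at 28.0 against 6.84, and IGSF10 at 5.04 against 0.68. GAPT was at 6.14 against 0.73 FPKM and EVA1B at 5.56 against 0.27. The remaining genes of this group share sequence or position with others. RPS10-NUDT3 is a read-through gene, annotated across RPS10 and NUDT3; PDCD6-AHRR is named as one but in the table overlaps AHRR and not PDCD6. PDCD6-AHRR had 4308 counts against 3, a ratio of 1415 (484 to 6864), and RPS10-NUDT3 had 24562 against 5639. Summed over each gene and those overlapping it on the same strand (below, the locus), counts relative to the library total differed by a log2 ratio of 0.04 for PDCD6-AHRR and 0.03 for RPS10-NUDT3. RPS10 itself was lower in resistant cells (237 against 329 FPKM), and so were AHRR (1.31 against 2.88 FPKM) and an overlapping gene without a symbol (3498 against 6825 counts). PDCD6, NUDT3, AHRR, the gene without a symbol, ASNSD1 and SGK3 were named after their values were seen. ASDURF overlaps ASNSD1 on the same strand; it had 251 counts against 14 and the locus sum differed by 0.21. UPK3BL1 had 570 counts against 86, while its locus with overlapping copies was lower in resistant cells (-0.59).

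Among the 12 lowest, besides S100A9, S100A8 and PRDX2, were 2 transcription factor genes, BHLHE22 (0.99 against 12.1 FPKM) and DMRTA2 (1.60 against 13.4 FPKM). SAP30, a subunit of the SIN3A histone deacetylase complex, was at 1.02 against 10.5 FPKM. The matrix proteoglycan gene VCAN was 5.92-fold lower (5.51 to 6.36) and the carboxypeptidase gene CPVL 5.65-fold lower (4.91 to 6.52). NAP1L5 was at 0.64 against 5.48 FPKM, BEX3 at 12.1 against 50.0, and NUDT10 at 0.73 against 5.19. The read-through gene C8orf44-SGK3 was at 0.73 against 7.75 FPKM, while SGK3 was higher in resistant cells (13.4 against 6.88) and the locus sum differed by a log2 ratio of 0.32.

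The m6A regulators were at similar levels in both libraries. Of 32 measured writers, erasers and readers, 30 were expressed, and none was 1.5-fold or more apart on the FPKM + 1 scale. This rule can miss differences of that size: 10 of 50 simulated genes with a true 1.5-fold difference passed it. Those simulated genes had a mean of at least 5 FPKM. Regulators below that level, such as FTO and ZCCHC4, were not covered, and the pseudocount shrinks their ratios more. METTL14, the partner of METTL3 in the methyltransferase, was the highest in resistant cells relative to parental (4.96 against 3.52 FPKM, 1.41-fold, 1.33 to 1.51), and ZCCHC4, a methyltransferase of ribosomal RNA, was the lowest (1.63 against 2.24 FPKM, 0.731-fold, 0.649 to 0.823). The median log2 ratio was -0.04, with 9 genes above 0 and 21 below. The counting interval excluded equal levels for 21 of the 30, and none lay outside the central 95% of the genes of its own expression bin.

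Among the other writers, the catalytic subunit METTL3 stood at 9.59 FPKM in resistant and 10.8 in parental cells, and the adaptor WTAP at 16.8 and 14. In the same order, VIRMA stood at 11.3 and 11.7, RBM15 at 7.19 and 7.57, RBM15B at 14.8 and 16.6, ZC3H13 at 12.8 and 11.6, and CBLL1 at 7.99 and 8.04. METTL16 stood at 4.57 and 4.19, METTL5 at 9.88 and 11.1, PCIF1 at 6.26 and 7.13, and TRMT112 at 29.3 and 33.0. The demethylase ALKBH5 stood at 10.3 and 8.69 FPKM (1.19-fold, 1.12 to 1.26) and FTO at 1.69 and 1.73. Of the YTH readers, YTHDF1 stood at 26.1 and 26.8, YTHDF2 at 28.0 and 30.9, YTHDF3 at 19.2 and 18.9, YTHDC1 at 13.6 and 14.3, and YTHDC2 at 5.45 and 5.59. IGF2BP2 stood at 14.8 and 14.9, whereas IGF2BP1 had 6 and 10 counts and IGF2BP3 had 0 in both libraries, which allows up to 3 counts each. HNRNPA2B1 stood at 145 and 175 (log2 ratio -0.26), HNRNPC at 74.2 and 84.2, RBMX at 52.1 and 54.6, PRRC2A at 81.9 and 94.7, and LRPPRC at 42.7 and 47.1. FMR1 stood at 5.41 and 4.99, ELAVL1 at 18.7 and 19.1, EIF3A at 91.7 and 90.1, and G3BP1 at 26.6 and 24.0. As lists, the 13 expressed writers (median log2 ratio -0.07, percentile 20.3) and the 15 expressed readers (-0.03, percentile 27.6) lay inside the random range; the 2 erasers had a median of 0.10.

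**Figure D2:**
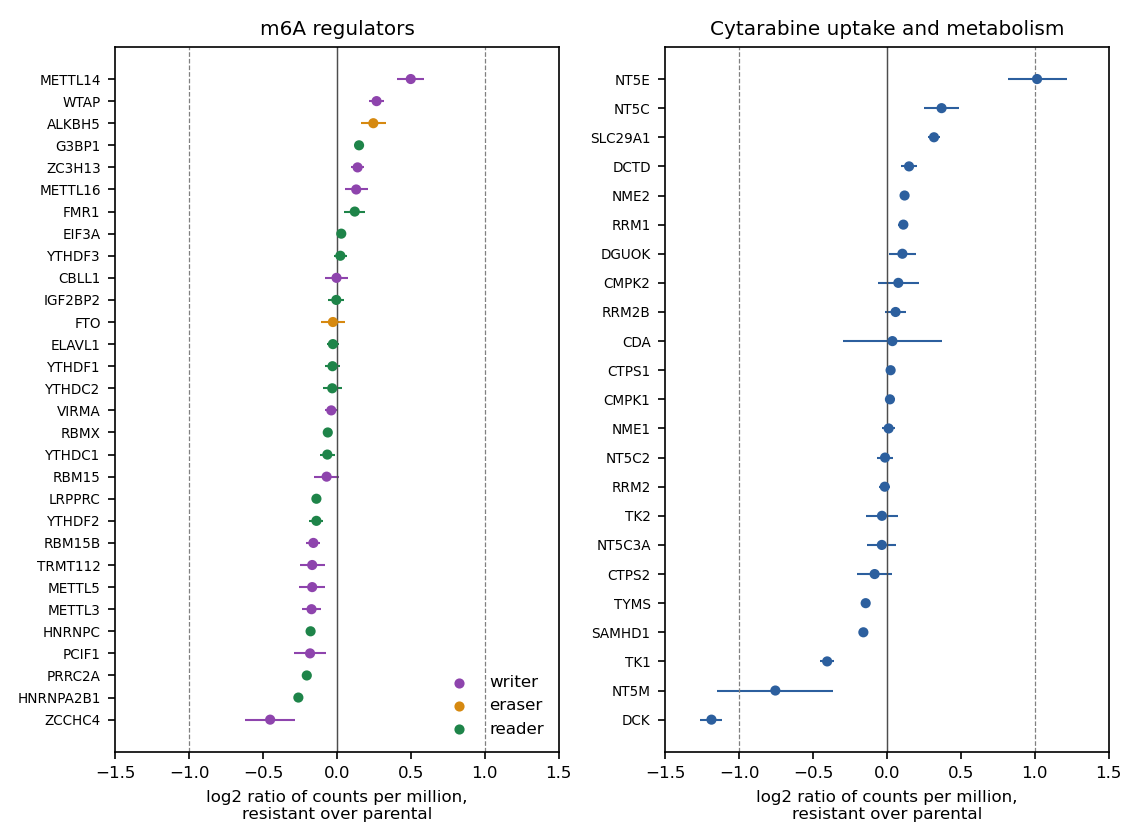
Points give the log2 ratio of counts relative to the library total, resistant over parental, for the 30 expressed m6A regulators (left) and 23 expressed cytarabine genes (right), and bars the exact 95% counting interval. Dashed lines mark a 2-fold difference; DCK lies below the lower line, and NT5E lies next to the upper line.

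Among the genes of cytarabine uptake and metabolism, DCK stood apart. DCK encodes deoxycytidine kinase, which carries out the first phosphorylation that activates cytarabine, and lies on chromosome 4 from 70992538 to 71030914 (GRCh38). It was at 10.0 FPKM in resistant and 22.9 FPKM in parental cells, from 2112 and 4739 counts, a fold of 0.439 (0.417 to 0.462). No other of the 23 expressed genes of this list was 2-fold apart on the FPKM + 1 scale, and the list as a whole lay inside the random range (median 0.02, percentile 69.1). NT5E, an ecto-nucleotidase, was higher in resistant cells (2.07 against 1.02 FPKM; 2.02-fold by counts, 1.76 to 2.32, and a log2 ratio of 0.60 with the pseudocount).

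The nucleoside transporter SLC29A1 was at 36.5 FPKM in resistant and 29.4 in parental cells, and SLC29A2 at 0.25 and 0.26. In the same order, the deaminase CDA was at 2.71 and 2.65, DCTD at 22.5 and 20.3, and SAMHD1, which hydrolyses deoxynucleoside triphosphates, at 30.2 and 33.8. The nucleotidase NT5C was at 13.1 and 10.2, NT5C2 at 8.90 and 8.99, NT5C3A at 7.13 and 7.32, and NT5M at 0.66 and 1.12. Ribonucleotide reductase was at 52.7 and 48.9 for RRM1, 18.1 and 18.3 for RRM2, and 8.66 and 8.34 for RRM2B. Among other kinases, CMPK1 was at 52.4 and 51.8, CMPK2 at 2.96 and 2.82, NME1 at 34.4 and 34.2, NME2 at 93.7 and 86.5, DGUOK at 19.7 and 18.3, TK1 at 55.2 and 73.2, and TK2 at 2.83 and 2.89. TYMS was at 95.5 and 106, CTPS1 at 65.6 and 64.6, and CTPS2 at 3.03 and 3.21. The 7 expressed drug efflux transporters lay inside the random range (percentile 87.9), with ABCC6 at 0.97 and 1.57, ABCC1 at 6.57 and 8.46, and ABCA2 at 27.5 and 24.97.

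Of 32 lists with a percentile, 6 lay below the random range and 4 above it. By chance 1.6 would lie outside if the genes of a list varied independently. That condition was not tested, so the excess is a description only. The lists of proliferation, cholesterol synthesis and myeloid differentiation were low in resistant cells. Of 37 proliferation genes, 35 were below 0, with a median log2 ratio of -0.18 (percentile 0); the kinase AURKA was at 23.3 against 34.3 FPKM and the replication helicase subunit MCM3 at 127 against 179, while cyclin CCNE2 was higher (16.7 against 11.96). None of these genes was 1.5-fold apart. The 23 cholesterol synthesis genes had a median of -0.26 (percentile 0), with TM7SF2 at 1.54 against 3.24 FPKM and EBP at 17.5 against 26.2. The 23 myeloid differentiation genes had a median of -0.15 (percentile 0.31), and 4 were at least 2-fold lower: S100A9, S100A8, VCAN and the lysozyme gene LYZ (95.8 against 225 FPKM). The granule protease CTSG, named after its value was seen, was higher (306 against 155 FPKM).

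Replication stress and DNA repair genes were also low as a list (50 genes, median -0.11, percentile 0.41), with CDC25A at 15.95 against 20.9 FPKM, BRCA1 at 11.9 against 15.6 and TIMELESS at 16.01 against 20.6. The p53 targets had a median of -0.18 (19 genes, percentile 1.05); the death receptor TNFRSF10B was at 2.92 against 5.84 FPKM and DDB2 at 2.42 against 4.14, while the cell cycle inhibitor CDKN1A was at 7.98 against 5.45. Fatty acid oxidation genes had a median of -0.13 (24 genes, percentile 1.11), with CPT1B at 1.92 against 3.90, ACAA2 at 3.93 against 6.34 and PPARA at 0.65 against 1.44. With a pseudocount of 5 FPKM the p53 targets, and with a minimum of 5 FPKM fatty acid oxidation, came inside the random range.

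Cytosolic ribosomal protein genes were higher as a list in resistant cells: 65 of 67 were above 0, with a median of 0.18 (percentile 100). The exceptions were RPL9 (38.6 against 56.3 FPKM) and RPS10, whose locus holds the read-through gene. RPL27A, the highest of the list, was at 109 against 77.9 FPKM. It lies in a part of chromosome 11 where 127 expressed genes had a median log2 ratio of 0.26. The share of mitochondrial ribosomal RNA, 0.741% against 0.552%, was also higher in the resistant library. Lysosome and autophagy genes had a median of 0.12 (31 genes, percentile 99.7), with the cathepsins CTSL at 50.3 against 24.9 FPKM and CTSD at 47.0 against 25.9, while CTSB was lower (9.52 against 14.9). Genes of the unfolded protein and integrated stress response had a median of 0.12 (18 genes, percentile 98.4), with CHAC1 at 1.41 against 0.52, ASNS at 5.98 against 4.05 and SEL1L at 10.9 against 7.80. The 8 class II antigen presentation genes had a median of 0.16 (percentile 97.5) at the edge of the random range, and came inside it in 5 of 8 alternatives; HLA-DRA was at 21.1 against 14.3, HLA-DRB5 at 23.9 against 18.1 and HLA-DMA at 1.58 against 2.20. With no filter on low values the lysosome list, and with a minimum of 5 FPKM the stress response list, came inside the random range.

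**Figure D3:**
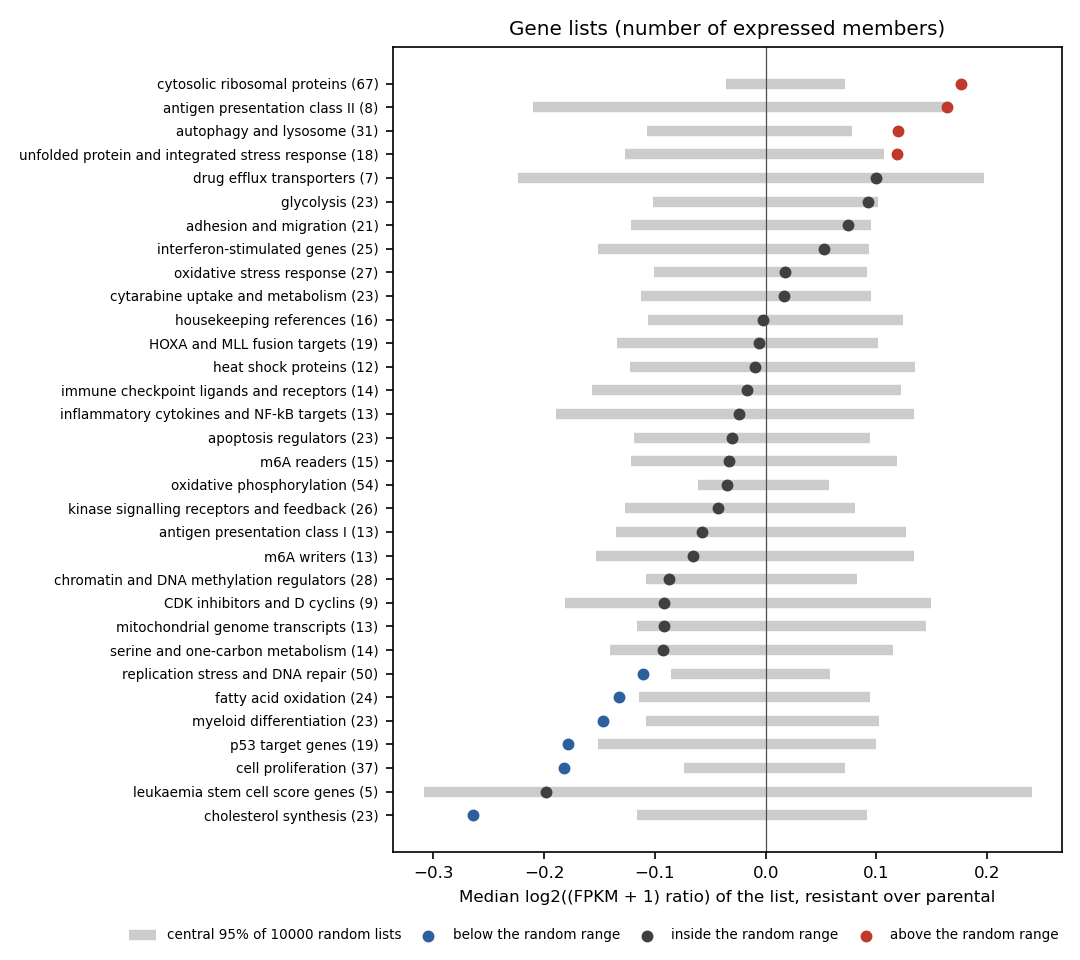
Points give the median log2((FPKM + 1) ratio), resistant over parental, of each of 32 gene lists, with the number of expressed members in brackets, and grey bars the central 95% of 10000 random lists matched on expression. Cholesterol synthesis (-0.26) is the lowest and cytosolic ribosomal proteins (0.18) the highest of the 32 medians.

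With the settings fixed beforehand the other lists lay inside the random range, although single members stood out. Among kinase signalling receptors and feedback genes (26 genes, percentile 35.7), AXL was higher, while FOS (5.15 against 16.7 FPKM) and ETV4 (1.63 against 4.01) were lower. Among adhesion genes (21 genes, percentile 94.7), the intermediate filament gene VIM was lower (43.6 against 129 FPKM), CX3CR1 was at 3.28 against 5.49, and ITGA4 was at 25.4 against 16.4. The median of the adhesion list was 0.07, but -0.13 (percentile 2.54) with a minimum of 5 FPKM. Among interferon-stimulated genes (25 genes, percentile 90.3), IFI27 and IFI6 (13.6 against 5.72 FPKM) were at least 2-fold higher and HERC5 was at 0.90 against 2.52. The median of that list was 0.05, but 0.43 (9 genes, percentile 100) with a minimum of 5 FPKM, and without a filter it lay at percentile 98.2. Among oxidative stress genes (27 genes, percentile 68.2), AKR1C2, which has near-identical relatives, had 865 counts against 6; ferritin heavy chain FTH1 was at 160 against 89.8 FPKM and GSTM3 at 3.13 against 5.07. Apoptosis regulators (23 genes, percentile 37.9) held APAF1, a core of the apoptosome, at 10.0 against 17.8 and BIK at 32.4 against 18.7. Inflammatory genes (13 genes, percentile 47.8) held CCL5 at 26.9 against 13.5, IL1RN at 2.25 against 5.08 and TNFAIP2 at 9.79 against 17.9; the median was -0.02, but 0.04 (percentile 97.6) without a filter.

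Genes of the HOXA cluster and KMT2A fusion targets (19 genes, percentile 54.7) held RUNX2 at 2.88 against 6.01 FPKM, PSIP1 at 15.6 against 21.1 and MYB at 129 against 98.4. The 5 expressed genes of a leukaemia stem cell score (percentile 8.31) included BEX3, ZBTB46 (1.08 against 0.40) and LAPTM4B (43.6 against 51.4). Glycolysis genes (23 genes, percentile 96.3) held ALDOC at 16.4 against 10.2, HK3 at 2.37 against 1.23 and SLC2A5 at 17.7 against 12.3; without a filter this list lay at percentile 98.9, and with unmatched random lists at 97.7. Oxidative phosphorylation (54 genes, percentile 12.9) held SDHA at 19.3 against 25.9, SDHB at 30.1 against 24.6 and NDUFS7 at 4.31 against 5.38. Serine and one-carbon genes (14 genes, percentile 10.6) held PSPH at 4.15 against 7.28. Cell cycle inhibitors and D cyclins (9 genes, percentile 16.7) held RB1 at 11.3 against 16.8 and CDKN2D at 4.40 against 2.89.

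Chromatin regulators (28 genes, percentile 6.11) held CREBBP at 4.95 against 7.05 FPKM, BMI1 at 20.8 against 26.4 and IDH2 at 63.0 against 76.9. Mitochondrial genome transcripts (13 genes, percentile 5.24) held MT-ATP6 with a log2 ratio of -0.21, MT-ATP8 with -0.15 and MT-CYB with -0.13. Heat shock proteins (12 genes, percentile 40.2) held HSPB1 at 88.3 against 108, BAG3 at 10.2 against 12.03 and HSP90AB1 at 891 against 1035. Class I antigen presentation (13 genes, percentile 19.6) held TAPBP at 22.3 against 28.3, HLA-E at 25.7 against 32.6 and PSMB10 at 42.5 against 50.01. Immune checkpoint genes (14 genes, percentile 49.7) held ULBP2 at 3.15 against 1.88, LILRB1 at 1.56 against 2.52 and SIGLEC10 at 2.16 against 1.39. The 16 housekeeping references had a median of -0.002 (percentile 41.5), with TUBB at 286 against 388 and HPRT1 at 50.9 against 39.7.

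Markers of other blood lineages were scarce in both libraries. Erythroid TFR2 was at 0.82 against 1.20 FPKM and EPOR at 1.51 against 1.95; megakaryocyte GP1BB was at 0.54 against 1.70 and GP1BA at 0.60 against 1.23. T and natural killer cell markers were limited to NKG7 (10.5 against 11.3 FPKM) and IL7R (1.87 against 1.75). Of the replication-dependent histones, H1-2 was at 3.30 against 6.21 and H4C14 at 1.10 against 0.68. In the B and plasma cell and the epithelial and fibroblast lists, 0 genes reached 1 FPKM.

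Genes of the short arm of chromosome 4 and the adjoining long arm were lower together in resistant cells, a pattern seen after the planned comparisons. From the start of the chromosome to IGFBP7, whose end lies at 57110385 (GRCh38), 138 of 144 expressed genes were below 0, with a median log2 ratio of -0.57 and quartiles of -0.73 and -0.44. Named after their values were seen, the histone methyltransferase gene NSD2 was at 7.66 against 17.4 FPKM, the replication factor gene RFC1 at 10.6 against 20.4, the purine synthesis gene PAICS at 29.9 against 47.2 and IGFBP7 at 34.4 against 69.8. Beyond IGFBP7 the median of 223 genes was -0.002, with 112 below 0. ZCCHC4, the lowest of the m6A regulators, and RPL9, the lowest ribosomal protein gene, lie before the break, whereas DCK, SAP30, NAP1L5, PRSS12 and METTL14 lie after it. Windows of 15 genes starting at DGKQ, RAC1P2 and NKX3-2 had medians of -0.73, -0.68 and -0.58, and 0 of 1000 shuffles of gene order gave a window as low anywhere.

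**Figure D4:**
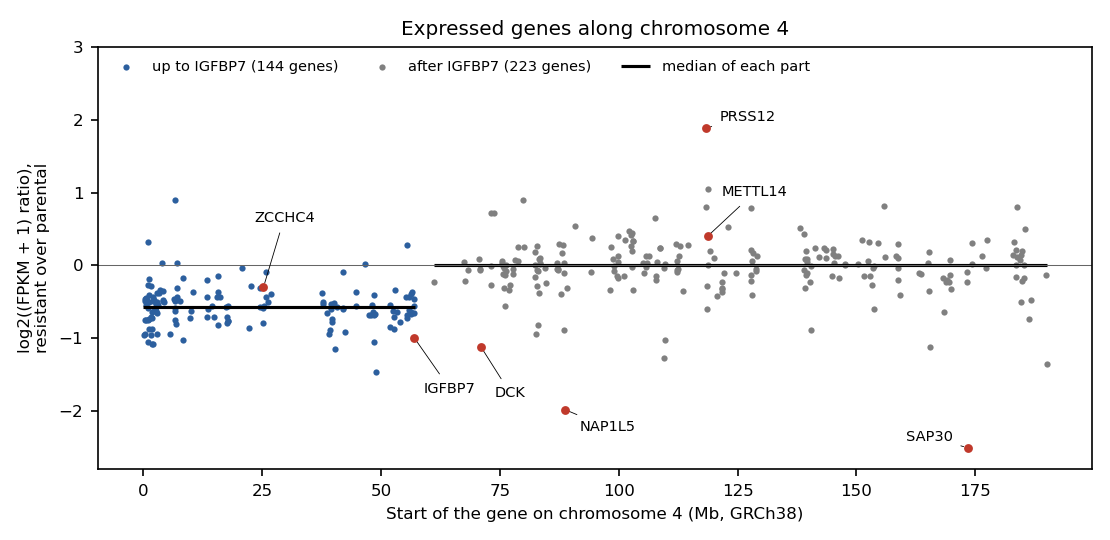
Each point is an expressed gene, with its start on chromosome 4 in Mb (GRCh38) on the x axis and its log2((FPKM + 1) ratio), resistant over parental, on the y axis. Black lines give the median of the 144 genes up to IGFBP7 (-0.57) and of the 223 genes after it (-0.002); red points are named genes.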

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

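The alternatives with CPM, without overlapping genes, without chromosome 4 and with random lists of protein-coding genes were chosen after seeing the data; the others were set beforehand. A count is called the same within 1.5 times its first value, a correlation within 0.01, the m6A median within 1 SD of the regulators, and a list median when it kept its sign and its side of the random range, whatever its size. By this, 255 of the values that answer a comparison were the same under an alternative, 30 moved, 9 list medians came inside the random range, 4 went outside it, and 1 changed sign and went outside it. The sign part of this rule was set after the values were seen. No list outside the range in the report changed sign. Inside it, the adhesion list turned from 0.07 to -0.13 and the oxidative stress list from 0.018 to -0.0037 with a minimum of 5 FPKM. The latter was -0.018 without a filter and -0.0037 without chromosome 4. After scaling to a median of 0, HOXA and fusion targets (-0.006) were at 0.0076, heat shock proteins (-0.0093) at 0.0064 and housekeeping references (-0.002) at 0.014. The 212 genes at least 2-fold apart (72 higher, 140 lower) became 592 (226 and 366) with a pseudocount of 0.1 FPKM, 30 (14 and 16) with 5 FPKM, 89 (36 and 53) with a minimum of 5 FPKM, and 95 (35 and 60) with a minimum of 1 FPKM in both libraries. They became 477 (191 and 286) with values rescaled to a common sum, 375 (112 and 263) with CPM, and 22 (12 and 10) with a 4-fold rule. Rescaling to a common sum multiplies the values and so acts like a smaller pseudocount. Without genes that overlap another on the same strand they were 146 (42 and 104), and without chromosome 4 the counts were 70 and 126. Of the genes past the rule, 34.0% were higher, 28.8% without overlapping genes, 46.7% with a pseudocount of 5 FPKM and 54.5% with the 4-fold rule; scaling to a median of 0 gave 36.6%. Dropping the filter added no gene past the rule, because with this pseudocount a gene below 1 FPKM in both libraries cannot reach 2-fold. Pearson's r was 0.957 with 0.1 FPKM.

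With a pseudocount of 5 FPKM, p53 targets (-0.085) and class II genes (0.10) came inside the random range. With a minimum of 5 FPKM, fatty acid oxidation (-0.13), the stress response list (0.11) and class II genes (0.15) came inside it and interferon-stimulated genes (0.43, 9 members) went above it. Without a filter, autophagy and lysosome (0.056) came inside, and glycolysis (0.092), interferon-stimulated genes (0.068) and inflammatory genes (0.043, from -0.024) went above it. With unmatched random lists glycolysis (0.093) went above and class II genes (0.16) came inside. Class II genes also came inside after rescaling (0.18) and without chromosome 4 (0.16). The cause of these shifts was not tested. Cell proliferation, cholesterol synthesis, myeloid differentiation, replication stress and ribosomal proteins stayed outside the range in all 8 alternatives run for lists. No m6A regulator reached 1.5-fold in either alternative run for them, and DCK ranged from -1.18 to -1.10. With 1 library per group no library could be left out, and the alternatives for several columns per sample were not run, as each sample had 1 column of each unit. No paired analysis was possible because each group holds 1 library. Depth limits low genes: 96 counts in parental cells gave IFI27 an interval of 15.7 to 23.9.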

Other observations

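The term scan and the windows were chosen only after the data were seen; the tests of the 3 patterns below were fixed before their results were seen. Among 2977 gene ontology and pathway terms of the table, 245 lay below and 84 above the central 95% of random lists matched on expression. By chance 149 in all would lie outside if the genes of a term varied independently, which was not tested. All genes named in this and the next paragraph outside the planned rule were named after their values were seen. The immune response term lay above the random range (median 0.13, percentile 100), with 80 of 128 genes above 0. Its larger differences went both ways: 15 genes were at least 1.5-fold higher in resistant cells and 8 at least 1.5-fold lower. Complement C3 was at 5.57 against 1.05 FPKM and the chemokine CCL23 at 6.16 against 1.4, while the defensin DEFB1 was at 0.52 against 2.83 and the protease inhibitor SLPI at 30.5 against 66.1. Of 15 genes of chondroitin and dermatan sulfate synthesis, 13 were above 0 (median 0.29), including the sulfotransferase CHST12 (1.88 against 1.00 FPKM) and CHPF (3.49 against 2.17). The 11 genes of defence against fungi had a median of -0.35; beside S100A9 and S100A8, MPO was at 0.94 against 2.81 and S100A12 at 0.58 against 1.95, while CTSG was higher.

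Smaller regional shifts appeared elsewhere. On chromosome 11, 127 genes up to DEPDC7 had a median log2 ratio of 0.26, with 18 below 0, and the 499 genes after it a median of -0.02. On chromosome 13, 50 genes from STK24 onward had a median of 0.36 against -0.05 before. On chromosome 12, 15 genes from KIF21A to SCAF11 had a median of 0.51, with 2 below 0, and 0 of 1000 shuffles gave a window as high. On chromosome 6, 326 genes up to SDHAF4 had a median of -0.18 and 236 after it 0.14. The breaks on chromosomes 11, 13 and 6 were placed where they fitted best and were not set against shuffles. The strongest windows of 15 genes in these parts were reached by 2 of 1000 shuffles on chromosome 11 and 7 on chromosome 13. For 2 windows on chromosome 6 it was 5 and 10. On the X chromosome, 15 genes from TMSB15A to MORC4, which include BEX3 (-1.96), TMSB15A (-1.68) and TCEAL9 (-1.02), had a median of -0.55, and 1 of 1000 shuffles gave a window as low.

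The genes of chromosome 4 up to IGFBP7 were lower together, at 0.673 of the parental level at the median on the FPKM + 1 scale. A candidate explanation is a lower copy number of this part in the resistant cells. It predicts that rows not used to find the pattern, without a symbol or below 1 FPKM, are lower too: 71 of 85 such rows with at least 20 counts were, with a median log2 ratio of CPM of -0.84 (resampled 95% range -1.15 to -0.56), against -0.25 for 180 such rows after the break and -0.08 on other chromosomes. A trend with gene length or GC content is argued against by random sets of other genes matched on expression and either property. Their medians centred on -0.021 for length and -0.021 for GC content, beside -0.57 for the 144 genes. The percentile of 0 among these sets adds little, because the break was placed by the low values of the 144 genes. The resampled range treats the 85 rows as independent, which neighbouring rows need not be, and covers no spread between cultures. The 85 rows were not checked for overlap with the 144 genes, so some may share reads with them. Regulation shared across the region predicts the same drop and stays open, as no DNA was measured.

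DCK was at less than 0.5 of its parental level. A loss of the wider region is argued against: the median log2 ratio of the 3 expressed genes within 2 Mb (UTP3, GRSF1 and MOB1B) was -0.057, and DCK starts 13.9 Mb beyond IGFBP7. All 3 lie on one side; on the other, the nearest expressed genes COX18 and ANKRD17 were at -0.27 and -0.01; these neighbours were named after their values were seen. Among 400 genes of similar length or GC content DCK lay no higher than percentile 1.12. DCK was singled out for its low value and would rank low in most sets of genes. This rank therefore does not decide on a trend with length or GC content. No gene of the table overlaps DCK, so the test of counts moved to an overlapping gene (0%) had no gene to run on and decides nothing, which was recognised after its result was seen. A difference between resistant and parental cells limited to DCK stays open and was not tested.

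The ribosomal protein genes were higher as a list. A trend with length or GC content is argued against, as the list stayed at percentile 100, above every random list matched on expression and either property. Reads moving from pseudogenes to their parent genes are argued against as the whole account. The 459 ribosomal protein pseudogenes held 99294 counts in parental cells, too few for the rise at the genes from 3.04e+06 to 3.48e+06 counts. Together these pseudogenes were higher, not lower, in resistant cells (log2 ratio of summed CPM 0.11), beside 0.17 for the genes. That sign cannot decide on a smaller movement, since the handling of reads that map to several places was not given. A difference between the cells and a difference between library preparations both stay open and were not tested, since each group has 1 library; the share of mitochondrial ribosomal RNA was 0.741% in resistant and 0.552% in parental cells.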
